A study of Hydra vulgaris with 11 samples.

How the data were processed

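RNA from whole adult polyps of *Hydra vulgaris* strain AEP, a freshwater cnidarian, was measured on custom Agilent arrays with 1 colour (Cy3). There were 11 arrays from 3 groups, 3 of control polyps, 4 of MyD88 knockdown polyps and 4 of germ-free control polyps. Per the labels' protocols, each sample held 15 polyps without buds or sexual differentiation, kept at 18 °C and fed *Artemia*, RNA was isolated with TRIZOL, and 100 ng of it was labelled. Groups and replicate numbers were taken from the labels.

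The values are spot intensities on a linear scale, which the authors made with Agilent Feature Extraction 10.7, per the submitters' processing notes. The processed intensity of the deposited scanner files was already background-subtracted and detrended, with surrogate values for signals near background, per the file headers, and was not yet set on a common scale between arrays. Germ-free control replicates 3 and 4 came in a shorter format without the columns of mean signal and local background. The series matrix was compared with the scanner files array by array. Its values were the processed intensities rounded, on a linear scale and not centred, with differences of at most 0.497% on any of 45208 spots. Their medians per array ran from 111 to 141 intensity units.

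Each array held 43113 probes of 60 bases on 43791 spots, next to 1417 control spots. Every probe was described as unknown and none had a coordinate, so that the files pair no probe with a gene. The reference table given with the series pairs gene identifiers with symbols and holds no sequences, and 0 probes could be given a coordinate. The MyD88 transcript, the GFP marker and the gene lists fixed beforehand were therefore not analysed here, and the knockdown itself was not checked. Probes are given by the name in the files. The names carry marks such as un and rc whose meaning is not given in the sources used here.

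For each array, log2 of the processed intensity was taken and the array's 75th percentile subtracted. Control spots and outlier-marked spots were left out, which removed 31 to 52 spots per array as outliers, and spots of 1 probe were averaged. No spot was saturated. A probe was tested when it was well above background on at least 3 of the 11 arrays, which 33939 probes were. Levels are log2 units relative to the array's 75th percentile. The 75th percentile itself lay between log2 intensities of 9.75 and 10.03. The share of spots well above background ran from 70.8% to 81.2%, and the number of arrays limits the precision.

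Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit over all 11 arrays, so that the 3 groups shared each probe's estimate of spread, with 8 residual degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested probes within each comparison, and a probe was called at an adjusted p under 0.05. The comparisons were knockdown against control, germ-free control against control, and knockdown against germ-free control. The last of these is also the test of the difference between the effects of the first and second. The labels do not say that samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

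Where a probe was not well above background on any array of the dimmer group, the fold is a lower bound, written "at least". It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. A fitted log2 difference given beside a bound is no measure of size for such a probe.

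The rule for naming probes was fixed before the data were examined. It provided for MyD88, GFP and informative gene names, and, where probes have no gene name at all, for the 2 probes that rose most and the 2 that fell most in each comparison among called probes whose arrays of the 2 groups did not overlap. Only this last part could be used, and 1 probe that it names is not reported here. Probes named outside it are given as chosen after their values were seen. For probes named by the rule, the groups do not overlap, so a difference cannot reverse when arrays are left out. The same holds within 1 slide or extraction day. Leaving out an array of the third group leaves the difference itself unchanged.

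The fit was tested on simulated data before use, with 200 of 33867 probes changed by a known fold. In the knockdown against control comparison, 63.5% of probes changed 2-fold and 92.5% of those changed 4-fold were called. For germ-free control against control these were 65.0% and 92.0%, and for knockdown against germ-free control 73.0% and 93.5%. Each simulated comparison also called 5 to 16 unchanged probes, and no changed probe was called in the wrong direction.

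The files gave slide and scan day, and the labels an extraction day. Slide 1 held control replicate 1 and knockdown replicates 1 and 2. Slide 2 held control replicates 2 and 3. Slide 3 held knockdown replicates 3 and 4 and germ-free control replicates 1 and 2, and slide 4 germ-free control replicates 3 and 4. Slide 1 was scanned on the first of 3 scan days, slides 2 and 3 on the second and slide 4 on the third. By the labels, RNA of control replicate 1 and knockdown replicate 1 was extracted on the first of 3 days, that of germ-free control replicates 3 and 4 on the third and all other RNA on the second. The labelled extraction day of knockdown replicate 2 lies after the scan of its slide, so that its day is uncertain. Knockdown replicates 3 and 4 share a source label, and the descriptions of germ-free control replicates 3 and 4 name other hatchlings than their titles do.

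The alternatives tried were normexp background correction, quantile normalization, the series matrix values, other filters on dim probes, slide or extraction day as a block, a replicate number block, averaging of knockdown replicates 3 and 4, fits of only the 2 groups compared, array weights, a variance trend, a 2-fold minimum, leaving out each array in turn, and settings added after the data were seen. To judge the overlap of comparisons that share the control arrays, unchanged groups were simulated 50 times against them. Counts and sequence properties were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.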

Results

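A MyD88 hairpin had been injected into *Hydra* AEP embryos, and a hatchling that was mosaic for the GFP-marked transgene was propagated by budding. MyD88 is an adaptor protein of Toll-like receptor signalling, and a hairpin transcript lowers its target by RNA interference. Selection for GFP gave a culture of polyps that had lost the marker, used as control (n = 3 arrays), and one with the transgene in both ectoderm and endoderm, the knockdown (n = 4). The germ-free control (n = 4) was made of polyps without the marker that had been treated for 7 days with antibiotics at 50 µg/ml and then kept in sterile-filtered medium. Of 43113 probes, 33939 were bright enough to be tested. The median SD between arrays of a group was 0.15 log2 units in the control, 0.17 in the knockdown and 0.16 in the germ-free control.

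Arrays of 1 group on 1 slide were the most alike. The SD of their log2 differences over the tested probes was 0.25 to 0.31 over 5 pairs, against 0.42 to 0.61 for the 10 pairs of 1 group on different slides. Pairs of different groups had an SD of 0.52 to 0.58 on the same slide and of 0.37 to 0.70 on different slides. The first principal component held 33.2% of the variance and placed the 4 germ-free arrays at 37.6 to 54.3, and the control and knockdown arrays at −48.4 to −3.89. The second held 18.6% and placed both knockdown arrays of slide 1, at 40.3 and 41.0, far from those of slide 3, at −39.7 and −35.5. It did not follow the slide alone. The germ-free arrays of slide 3 lay at 19.8 and 17.1 and control replicate 1 of slide 1 at 10.1. The control arrays of slide 2, at −32.8 and −25.3, lay near the knockdown arrays of slide 3.

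**Figure D1:**
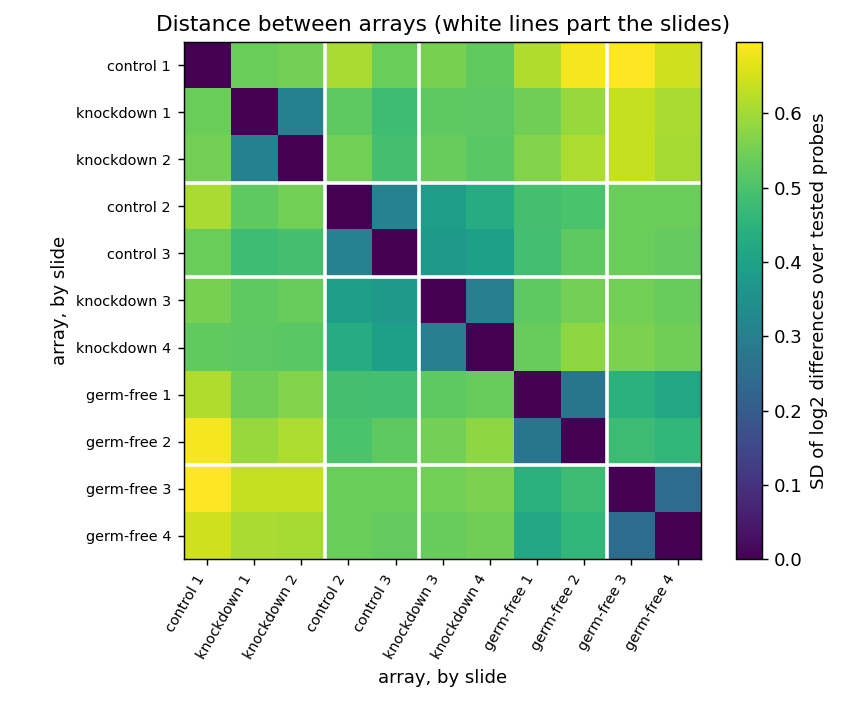
Distance between each pair of the 11 arrays, as the SD of their log2 differences over the tested probes (colour scale), with the arrays ordered by slide on both axes and white lines between slides. Pairs of 1 group on 1 slide lie at 0.25 to 0.31, and control replicate 1 lies at 0.61 from control replicate 2 and at 0.54 from control replicate 3.

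Knockdown against control polyps asks which transcripts differ when MyD88 is targeted. Of the tested probes, 13 were called, 6 higher and 7 lower in the knockdown. Probe un_37124 was not well above background on any control array (−7.39 ± 0.10, SD, n = 3) and stood at −1.88 ± 0.09 (n = 4) in the knockdown, at least 10.1-fold higher (log2 difference 5.51, SE 0.56, adjusted p = 0.0074). Probe 11960 rose 12.4-fold, from −2.05 ± 0.14 to 1.58 ± 0.11 (log2 difference 3.63, SE 0.09, adjusted p = 4.95e-08). Probe rc_1931 was 12.6-fold lower, at −4.78 ± 0.59 in the knockdown against −1.12 ± 0.17 in the control (log2 difference −3.66, SE 0.26, adjusted p = 0.00047). It was still well above background on 3 of the 4 knockdown arrays.

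On the germ-free arrays, probe 11960 stood at −2.28 ± 0.07 and rc_1931 at −1.35 ± 0.14 (n = 4), and neither was called against the control. Probe un_37124 stood at −6.88 ± 1.34 there and was well above background on 1 of the 4 germ-free arrays. The sequence of probe 11960 is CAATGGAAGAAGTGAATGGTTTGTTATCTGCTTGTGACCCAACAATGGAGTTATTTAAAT. That of rc_1931 is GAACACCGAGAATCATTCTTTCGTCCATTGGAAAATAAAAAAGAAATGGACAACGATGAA. No genome position or gene annotation goes with these sequences in the files used here.

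**Figure D2:**
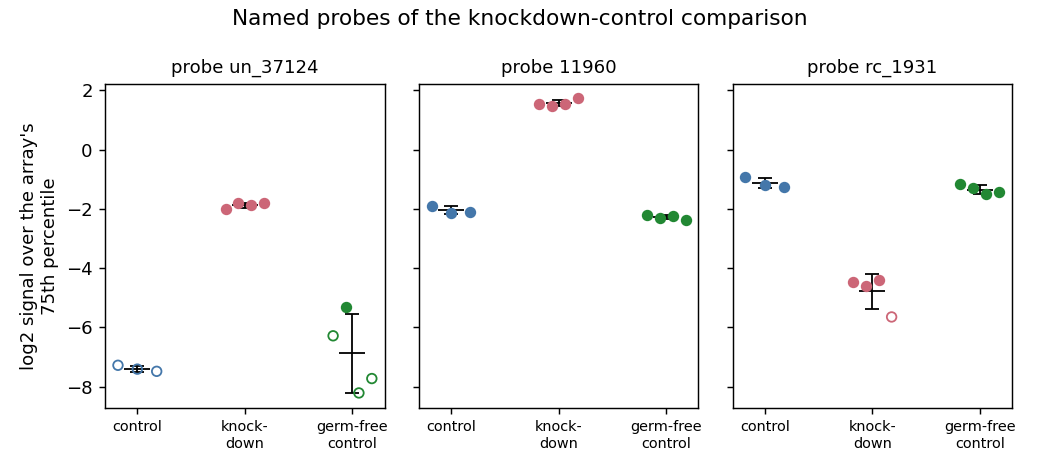
Log2 level over the array's 75th percentile of the 3 probes named for knockdown against control, with 1 point per array in the 3 groups, open where the probe was not well above background, and the mean ± SD of each group as bars. The 4 knockdown arrays of probe 11960 lie around 1.58 and those of rc_1931 around −4.78, apart from both other groups.

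Fitted log2 differences of the 13 probes ran from 0.59 to 5.51 in absolute value with a median of 2.10. The highest is that of un_37124, for which only the lower bound measures size. By the fitted difference 10 of the 13 were at least 2-fold, 5 in each direction. One of the 5 higher, un_36250, chosen after its values were seen, was not well above background on any control or knockdown array, so that its fold is not measured. At an unadjusted p under 0.05 there were 2679 probes, and an estimated 90.7% of the tested probes did not change. This estimate takes the arrays as independent. Over 33885 tested probes, the change on slide 1 and that on slides 2 and 3 had the same sign in 50.6% (r = −0.151). The latter cannot be told apart from a slide difference. The share not estimated as unchanged is therefore no measure of a knockdown effect. The changes of the 3 named probes on slide 1 were 5.37 for un_37124, 3.42 for 11960 and −3.60 for rc_1931. Over the arrays labelled with the second extraction day they were 5.61, 3.72 and −3.67. Both sets hold knockdown replicate 2, whose extraction day is uncertain.

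With slide as a fixed block 5485 probes were called, an estimate for which only slide 1 sets knockdown beside control, with 1 control array. In each comparison the fixed block takes its spread only from arrays of 1 group on 1 slide, which were the most alike. Its counts therefore leave out the larger spread of a group between slides. With arrays of 1 group on 1 slide as a random block 3 were called, of the named probes 11960 alone. The count was 7 without control replicate 2 or 3, knockdown replicate 1, 2 or 4 or germ-free control replicate 2, and 8 without germ-free control replicate 1, and un_37124 lost its call without control replicate 2 (adjusted p = 0.054) or 3 (adjusted p = 0.064). With normexp on the median signal the change was 2.28 for un_37124 and −2.17 for rc_1931.

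Germ-free against untreated control polyps asks which transcripts differ after antibiotic treatment of polyps without the transgene. There were 1794 called probes, 5.29% of those tested, 920 higher and 874 lower in the germ-free control (866 and 1246 after quantile normalization). Their median fitted change was 0.65 log2 units in size. Among the 418 calls of at least 2-fold by the fitted difference, 308 were higher and 110 lower. Probe 1669 rose at least 11.4-fold, from −7.25 ± 0.15 (SD, n = 3), not well above background on any control array, to −1.70 ± 0.40 (n = 4; adjusted p = 0.00057). Probe 22559 rose at least 14.1-fold, from −6.89 ± 0.96 to −1.39 ± 0.71 (adjusted p = 0.0079), and was well above background on 2 of the 4 knockdown arrays. Probe rc_37926 was at least 224-fold lower, at 1.76 ± 1.42 in the control and −8.35 ± 0.16 in the germ-free control, where no array was well above background (log2 difference −10.11, adjusted p = 1.87e-05, and −10.93 without control replicate 1). Probe 25542 was at least 109-fold lower, at 0.73 ± 0.56 against −8.24 ± 0.16 (adjusted p = 7.84e-06).

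A set of 13 probes was well above background on every control and knockdown array and on no germ-free array. Their mean levels lay between −4.84 and 1.76 in the control and between −8.35 and −6.48 in the germ-free control. Against the control they were lower by at least 2.31-fold to at least 224-fold, with a median bound of 52.6-fold. All 13 were called lower than in the knockdown and 12 lower than in the control. The exception, un_rc_2500, chosen after its values were seen, had an adjusted p of 0.061. None of the 13 was called between knockdown and control. These calls rest on the arrays on which the 13 were picked, so that they are no separate support. By the same measure, 77 probes were well above background on every array but the control arrays, and 2 on every array but those of the knockdown. In the other direction, 367 probes were well above background on every germ-free array and on no other array, of which 106 were called higher. The germ-free arrays had the lowest signals that counted as well above background, −6.25 to −5.86 against −5.65 to −5.02. At a common level of −5.02, 46 probes were above it on the germ-free arrays alone and 16 on all arrays but those.

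**Figure D3:**
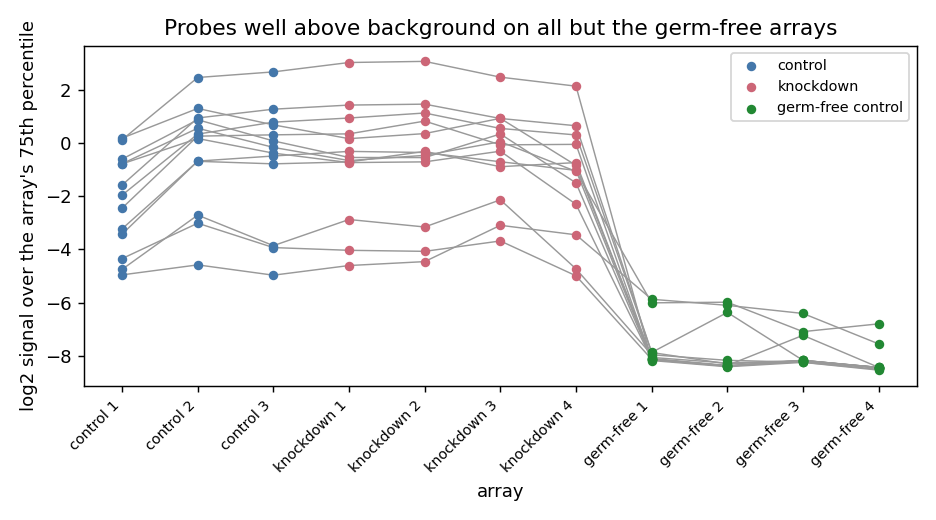
Log2 level over the array's 75th percentile, on each of the 11 arrays, of the 13 probes that were well above background on all but the germ-free arrays, with 1 line per probe and the groups in colour. The germ-free means lie between −8.35 and −6.48, and 7 of the 13 probes have their lowest control or knockdown level on control replicate 1.

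Within the second extraction day, which holds 2 control and 2 germ-free control arrays, the change was 5.49 for probe 1669, 5.61 for 22559, −10.88 for rc_37926 and −9.17 for 25542. No slide held both groups. The fixed slide block adds the slide 1 difference of knockdown from control replicate 1 to the slide 3 difference of germ-free control from knockdown. Control replicates 2 and 3 and germ-free control replicates 3 and 4 have no part in the changes it gives. With slide as a fixed block 9679 probes were called and with arrays of 1 group on 1 slide as a random block 48, with 22559 no longer called in either (log2 difference 1.26, adjusted p = 0.19, and 5.27, adjusted p = 0.096). The fixed block gave 3.58 for 1669, −7.68 for rc_37926 and −8.15 for 25542, and normexp on the median signal 2.34 for 1669, 2.5 for 22559, −5.76 for rc_37926 and −4.69 for 25542. The count was 705 without control replicate 1, 924 without control replicate 2, 296 without control replicate 3, 811 without germ-free control replicate 3 and 672 without germ-free control replicate 4.

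Knockdown against germ-free control polyps sets the effects of the transgene and of the antibiotics against each other. There were 1617 called probes, 711 higher and 906 lower in the knockdown (928 and 834 after quantile normalization), with a median change of 0.64 log2 units in size. Of the 456 at least 2-fold by the fitted difference, 114 were higher and 342 lower. Probe rc_37926 was at least 425-fold higher in the knockdown, at 2.68 ± 0.45 (n = 4; adjusted p = 3.61e-06), and probe 18585 at least 144-fold, at 1.12 ± 0.40 against −8.21 ± 0.24 (adjusted p = 2.42e-05). Probe rc_6748 was 44.6-fold lower in the knockdown, at −2.93 ± 1.94 against 2.55 ± 0.44 in the germ-free control (adjusted p = 0.0060), with the control at −1.58 ± 0.88. Probe rc_43606 was 32.8-fold lower, at −3.66 ± 1.62 against 1.38 ± 0.37 (adjusted p = 0.0026), with the control at −3.20 ± 0.15. On slide 3, which holds 2 arrays of each group, the changes were 10.61 for rc_37926, 8.89 for 18585, −4.01 for rc_6748 and −3.75 for rc_43606. Over the arrays labelled with the second extraction day they were 10.87, 9.11, −5.10 and −4.68. These include knockdown replicate 2 of slide 1, whose day is uncertain. All other arrays of the 2 groups with that label are on slide 3, so that this is no separate check.

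With slide as a fixed block 7056 probes were called and with arrays of 1 group on 1 slide as a random block 72, with rc_6748 no longer called in the latter (adjusted p = 0.082). For the fixed block, the difference comes from slide 3 alone and the spread only from arrays of 1 group on 1 slide. The 7056 therefore leave out the spread of a group between slides. Normexp on the median signal gave changes of 6.67 for rc_37926, 5.10 for 18585, −4.64 for rc_6748 and −3.98 for rc_43606, the fixed block −4.01 and −3.75 for the last pair, and rc_6748 was at −6.16 without knockdown replicate 4. The count was 968 without control replicate 3, 657, 634 and 730 without knockdown replicates 1, 2 and 4, and 1058, 767 and 689 without germ-free control replicates 2, 3 and 4.

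Of the 13 probes called between knockdown and control, 11 were also called between knockdown and germ-free control, each in the same direction, but on the same knockdown arrays, on which the 13 had been chosen. Between germ-free control and control, 3 of the 13 were called, 2 in the same direction as in the knockdown and 1 in the opposite one. These 3 are named after their values were seen. Probe 10154 was higher in both (log2 difference 0.59 with adjusted p = 0.027 in the knockdown, 0.39 with adjusted p = 0.019 in the germ-free control). Probe un_36250 was also called higher in both, but was well above background on the 4 germ-free arrays only, so that no fold is given. Probe rc_5146 rose by 1.76 in the knockdown (adjusted p = 0.027) and had a difference of −0.88 in the germ-free control (adjusted p = 0.047). Independent lists of these sizes would share 0.16 probes that were higher and 0.18 that were lower, and unchanged groups simulated against the same controls shared 0 to 0.10 on average. In these simulations no group was changed, so that they give no expected overlap for lists of the real sizes.

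**Figure D4:**
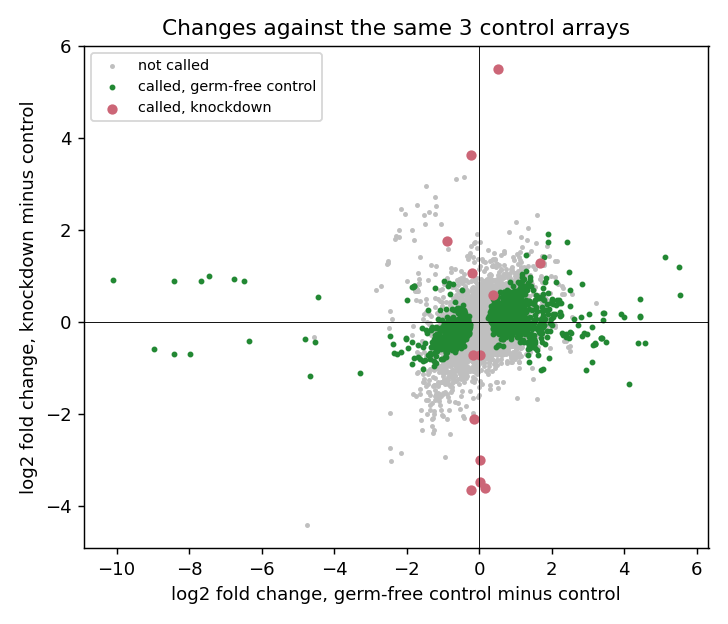
Log2 fold change of each tested probe in the germ-free control (x axis) and in the knockdown (y axis), both against the same 3 control arrays, with the 1794 probes called in the germ-free control in green and the 13 called in the knockdown in red. The red points run from −3.66 to 5.51 on the y axis, and the green points reach −10.11 on the x axis.

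Across the tested probes, which are not independent replicates, the changes in the knockdown and in the germ-free control correlated at r = 0.29. Unchanged groups simulated against the same controls gave 0.57 with independent noise and 0.53 with the arrays' own residuals. These simulations leave out that arrays of different groups share slides. The covariance was 0.0331, against 0.0288 and 0.0362 in these simulations. Part of the overlap may come from the shared control arrays, which are too few to be split into 2 parts of at least 2 arrays. The number called in both in the same direction was 4388 with slide as a fixed block, 0 without control replicate 2 or 3, knockdown replicate 1, 2 or 4 or germ-free control replicate 2 or 3, and 1 without germ-free control replicate 1 or 4. With the fixed block, both changes contain the same slide 1 difference between knockdown and control replicate 1. A large overlap is then built in, and the 4388 tell nothing of a shared effect.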

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

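Both values below were picked out by a check fixed before the data were examined, which asks whether 1 array of a group of 4 stands apart from the other 3, and no test was chosen after they were seen. Of 30 groups looked at, 2 had such an array, and chance gives about 1 in 20.

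Probe rc_1931 stood at −5.65 on knockdown replicate 4, below the nearest other knockdown array at −4.60, a gap of 0.845 of the whole range. It was not well above background on that array. The 75th percentile of germ-free control replicate 2 was 9.84 (log2 intensity), below the nearest other germ-free array at 9.97, a gap of 0.844 of the range.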

How the results depend on the processing

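Settings named as added were chosen after the data were seen. Counts of called probes are given for knockdown against control (13), germ-free control against control (1794) and knockdown against germ-free control (1617), in this order. Normexp background correction, possible on the 9 arrays with mean signals, gave 4 (0 higher), 0 and 2 (0 called in the same direction in both of the first comparisons, against 2), and all named probes but rc_37926 between knockdown and germ-free control and rc_1931 lost their call. On control replicate 3 a local background of up to 116116 intensity units, against a median of 21.0, displaced its fit. Without spots of a background over 100 (added) the counts were 21, 1474 and 1304 (6 in both), and with the 75th percentile on the same arrays (added) 9, 1590 and 1500. Slide as a random block gave 2719, 6983 and 6447, with a correlation of 0.77 within slides, and as a fixed block 5485, 9679 and 7056 (4388 in both). The spread in the fixed block comes only from arrays of 1 group on 1 slide. Arrays of 1 group on 1 slide as a random block (added) gave 3, 48 and 72 (0 in both). The 3 were probe 11960 and, chosen after their values were seen, rc_31250 (log2 difference −3.00) and 11552 (−2.10). Extraction day as a fixed block gave 2570 in the last comparison, and with knockdown replicate 2 moved to the first day (added) 195, 5424 and 4242. Arrays labelled with the second extraction day alone, knockdown replicate 2 among them, gave 4 in the first comparison.

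Array weights gave 57 and 8007 in the first and second comparisons, fits of only the 2 groups compared 6 and 790, and averaging knockdown replicates 3 and 4 gave 1038 in the last. Testing all probes gave 6808 (1632 higher, 5176 lower) and 6310 (4660 higher, 1650 lower) in the second and last, and a 2-fold minimum 418 and 456. Leaving out 1 array at a time gave 7 (without control replicate 2) to 12, 296 (without control replicate 3) to 1593 and 634 (without knockdown replicate 2) to 2301, 0 to 3 called in both, and 13 to 14 probes lost from the germ-free arrays alone (added). The replicate block gave 6 and 850, with 0 called in both, and 1229 in the last comparison. Samples were not taken as paired, since that was to need every same-numbered pair's correlation over 0.1, and these ran from −0.19 to 0.18, with 6 of 10 pairs over 0.1. Of the second comparison's calls, 920 were higher and 874 lower, against 866 and 1246 after quantile normalization, 682 and 1167 with normexp on the median signal (added), 2166 and 470 with extraction day as a block and 1102 and 172 on the second day alone. In the last comparison, with 711 higher and 906 lower, extraction day as a block gave 419 and 2151, the second day alone 223 and 1647 and normexp on the median signal 925 and 621, and this last setting gave 6 and 11 in the first. Of 242 alternative values of the 11 named differences, 224 kept direction and call, 18 the direction alone and 0 reversed. For settings that leave out an array, 0 reversed was fixed by the naming rule. Probe un_37124 lost its call in 5 of 22. Fitted differences moved more. With normexp on the median signal, whose offset of 50 draws dim values together, un_37124 went from 5.51 to 2.28. In the second comparison rc_37926 went from −10.11 to −5.76. For both probes no array of the dimmer group was well above background, so that these measure no size. Settings for MyD88 and the gene lists were not run, as no probe has a gene name. Signal over background limits the changes of dim probes to lower bounds. Apart from the displaced fit and the settings that use fewer arrays, the cause of these changes was not tested.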

Other observations

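The counts over other splits of the arrays were fixed before the data were examined, and all other tests in this part were chosen after the result they bear on was seen.

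Called probes of the germ-free control came partly from related sequences. The 920 that were higher formed 863 groups and the 874 that were lower 799 groups when probes sharing 25 bases were joined, with up to 29 probes in a group. For 1688 numbers, both the probe with the mark un and that with un_rc were tested. In the germ-free control both were called in the same direction for 29 numbers, where independent lists would give 4.34, and between knockdown and germ-free control for 27 (expected 2.26). In the knockdown none were, with 1 un probe and 0 un_rc probes of these 1688 numbers called by limma. Of tested probes marked un_rc, 6.49% were called in the germ-free control against 5.16% of other probes, and of those named by a number alone 4.83% against 5.59% (Fisher's exact test, adjusted p = 0.0085 for each, over 8 tests). This test takes probes as independent, which the shared sequences and the joint calls of un and un_rc probes go against.

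The 52 probes whose names begin with house had a median change of 0.02 log2 units in the knockdown and −0.12 in the germ-free control. By limma 0 of them were called in either, with 3 and 10 at an unadjusted p under 0.05, and 2 were called between knockdown and germ-free control, where 27 had an unadjusted p under 0.05 and the median change was 0.15.

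The 13 probes lost from the germ-free arrays were uneven across the other arrays. On control replicate 1, 7 of them had their lowest level, a median of −2.63 from the other arrays' median, and on knockdown replicate 4 another 5, at −1.27. Of all tested probes 21.1% and 11% were lowest on these arrays.

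For these 13 probes, the tables argue against a lower sensitivity of the germ-free arrays and against a slide difference. The lowest share of spots well above background on a germ-free array was 77.8%, above the highest of the other arrays, 75.6%. Picked in the same way without slide 3 were 21 probes, which include the 13. For these 21, knockdown lay above germ-free control on slide 3 by a median of 4.64 log2 units (range −0.23 to 10.6, higher in 19). The difference was over 1 log2 unit in 17. On the germ-free arrays of slide 3, 14 of the 21 were not well above background and 5 were, so that for those 5 a slide difference stays open. Of 100 draws of 4 single arrays 1 gave as many, the real one (real value 13, highest other 9), which excludes chance only as far as arrays of 1 slide count as independent. As a hypothesis, the 13 probes may read RNA of microbes that the antibiotics removed. Their mean GC content was 43.2% against 36.5% (SD 3.28) of tested probes (two-sided permutation p = 1e-05, the smallest that 100000 random sets can give). Of the 13, 10 had a GC content of at least 43%, as had 7.16% of tested probes. The others, 25542 among them, stood at 35%, the median of tested probes. For those the GC content gives the hypothesis no support. Of 8 stretches conserved in bacterial ribosomal RNA, searched in all probes, however, a match was found in only 1 of the 13, rc_37926. Matches were also found in 12 other tested probes that were not called (Fisher's exact p = 0.0050). Both p-values take the 13 probes as independent, though 7 shared control replicate 1 as their lowest array and 5 shared knockdown replicate 4. A response of the polyps to the antibiotics or to the loss of microbes stays open and was not tested.

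In the knockdown, 5485 probes were called with slide as a fixed block, on the spread between arrays of 1 group on 1 slide alone, and 13 without. Of the 35 splits of the control and knockdown arrays 3 gave 13 or more, so that chance is not excluded. The highest, 6514, parted the slide 1 arrays from the rest. This points to a structure of the samples by slide, scan day or, since the day of knockdown replicate 2 is uncertain, extraction day. These cannot be told apart here. With arrays of 1 group on 1 slide as a random block, 3 probes were still called, 11960 among them. A knockdown effect hidden by slide differences stays open: over 5475 probes called with the block, the change on slide 1, which rests on control replicate 1, and that on slides 2 and 3 correlated across probes at r = −0.267, but slide 2 holds only the control and slide 3 none of it, so that the latter cannot be told apart from a slide difference. The 13 called probes had the same direction on slide 1 and within the labelled second extraction day, which share knockdown replicate 2, but were chosen on these arrays. Of simulated 2-fold changes 63.5% were called, but with noise independent between arrays, and smaller changes were not simulated. The simulation changed 200 probes at once and called 137. The adjustment is stricter where fewer probes are called, so that with 13 calls the share may be lower. A difference between the separately kept cultures other than the transgene's effect may be part of the 13, and was not tested.

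The dimmest 8485 tested probes had 396 higher and 79 lower calls in the germ-free control (83.4% higher), where the brightest 8485 had 108 and 252. After quantile normalization they were 296 and 252 (54.0% higher), so that more calls were lower as well as fewer higher, with normexp on the median signal 85 and 77 (52.5%), and with arrays of 1 group on 1 slide as a random block 11 and 1 (91.7%). The brightness scale of the arrays may account for part of the excess of rises among dim probes. An effect of the treatment on weakly expressed transcripts stays open.

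Of the 35 splits of the germ-free and control arrays, 1 gave as many calls, the real one with 1794 (highest other 297). Of the 35 splits of the knockdown and germ-free arrays likewise 1 did, the real one with 1617. The highest other, 1008, set knockdown replicates 1 and 2 with germ-free control replicates 1 and 2 against the rest. This excludes chance only for splits of single arrays, since arrays of 1 group on 1 slide were more alike, and with these sets as a random block 48 and 72 probes were called.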
